A study of Homo sapiens with 27 samples.

How the data were processed

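Total RNA of HepAD38, a human hepatocellular carcinoma line that carries an HBV genome, was sequenced in 27 libraries in 9 groups of 3, per the labels. Per the labels' protocols, stranded libraries were made with an mRNA kit that adds unique molecular identifiers, and whether reads were deduplicated is not given in the sources used here. HISAT2, StringTie, DESeq and hg38 are named in the submitters' processing notes, without roles. The peak caller of the 4 antibody lists is not given in the sources used here. Whether the 3 libraries of a group came from separate cultures is not given either.

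For m1A, m5C, m7G and ac4C the authors deposited 1 list each, with RPM values of the IP and of the input per peak. The log2 enrichment deposited for each peak is the authors' own and is not the log2 of the RPM values' quotient. The deposited p-value of each peak and its adjusted value were used only to rank peaks. For Psi, peaks were called with MACS 2.2.6 on 3 libraries together without a control, per the file headers, keeping 1 tag per position at a q-value limit of 0.05. Its pileup signal, its fold over the local background and its −log10 of the p-value and q-value are those of the caller, per the file headers. Of 10921552 tags, 20.3% were left after filtering.

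The listed values were pooled over libraries, so no value per library was analysed here and no count model across replicates was run, unlike what was planned. All RPM values, 100%, were whole multiples of 1 read within 0.1 read. The depth recovered this way ran from 17135274 reads in the ac4C IP to 364905848 in the m1A input. The recovered reads gave RPM ratios with 95% exact (Clopper-Pearson) intervals. A named gene's ratio is that of 1 peak, the one with the highest authors' enrichment, though many genes had several. Where the input had 0 reads, a floor of 3 pooled counts gave a lower bound. Intervals and floors cover counting error only. An exact binomial test of IP against input reads, two-sided, with Benjamini-Hochberg adjustment within a list, was added after the files had been examined. It compares pooled libraries relative to their depths, so a higher or lower call refers to RPM and not to read numbers.

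Gene names are those of the files, updated through a RefSeq table of GRCh38.p14 with 59792 genes, of which 20056 are protein-coding. The Psi list names no genes, so a peak was given to the gene whose span holds it. Peaks that name several genes were left out of gene counts. Genes of the Y chromosome were left out of the named genes. Some genes that the rule below names are not reported here.

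Before the data were examined, 20 gene lists, the named-gene rule and the tests were fixed. For each modification the rule took the 10 genes with the strongest listed peak, up to 4 members of each list, the genes that write, erase or read that modification, and the 10 genes in all 5 lists with the smallest rank sum, besides mitochondrially encoded genes. Genes with the highest summed RPM, and ALB, APOA1 and TF in the account of ac4C, were named after their values were seen. A list of 27 fibroblast and mesenchymal markers was written after 3 of them had been seen in the ac4C list. The lists covered cytosolic ribosomal proteins, translation factors, plasma proteins, hepatic lipid and sterol synthesis, glycolysis, oxidative phosphorylation, mitochondrially encoded RNAs, histones, 6 lists of modification enzymes and readers, HBV host factors, innate RNA sensing, heat shock and unfolded protein response, cell cycle, spliceosome and SR proteins, and other liver cell types. The list of mitochondrially encoded RNAs was described but not tested, since the 4 antibody lists name no such gene. HBV sequence was not analysed here.

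Gene sharing was tested for 10 pairs and 19 gene lists by Fisher's exact test against protein-coding genes listed outside the pair or list. Odds ratios have a normal-approximation 95% CI, with 0.5 added to each cell where a cell was 0. No exon table was used here, so the ends of gene spans (within 500 bases) took the place of untranslated and coding parts. Peaks were placed at random 1000 times by 1 circular shift per gene, within stretches listed by the antibody lists outside the test and at least 200 bases long, which departs from the planned placement in exons. An earlier version used stretches that held the tested peaks themselves, so that the places open to a peak depended on the lists tested. It was replaced after its values were seen, and it is kept as an alternative. Confounding by expression was examined with Mantel-Haenszel odds ratios within 5 strata of input reads per base, which 88.6% to 100% of background genes had in the gene list tests. In the pair tests fewer had one where Psi was not in the pair, down to 8488 of 10185 for m1A with m5C. Alternatives also covered stricter lists, backgrounds, gene span, gene assignment, windows of 200 and 1000 bases, the overlap definition and the ac4C list.

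The tests were tested on simulated data. Unchanged lists for ac4C were called in 5% of 100 draws and lists with a planted odds ratio of 4 in 98%, over 11557 genes. The pair test of m1A with ac4C called 0 of 20 unchanged draws and 20 of 20 with an odds ratio of 3. Lists that followed gene level alone had a median odds ratio of 3.05, and of 1.16 within strata, where 10 of 100 were called, so strata do not remove all of such an effect. Of 20 random ac4C placements, 0 were called for overlap with m1A over 1465 genes and 1 for the 5' end over 2020 genes, and all 20 with planted overlap were called in either test. The binomial test recovered 86.0% of 200 peaks raised 2-fold for m1A, 84.5% for m5C, 96.5% for m7G and 31.5% for ac4C; at 1.2-fold it recovered 39.0%, 33.5%, 63.0% and 4.5%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.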

Results

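HepAD38, a human hepatocellular carcinoma line that carries a hepatitis B virus (HBV) genome, was profiled for 5 RNA modifications in 27 libraries. For N1-methyladenosine (m1A), 5-methylcytidine (m5C), 7-methylguanosine (m7G) and N4-acetylcytidine (ac4C), 3 immunoprecipitated (IP) and 3 input libraries were labelled per modification. For pseudouridine (Psi), 3 libraries were labelled, without saying whether they were IP or input. The stated purpose was to ask whether such modifications take part in evolution, and no other condition was compared. Each antibody list gave 1 pooled IP value and 1 pooled input value per peak, scaled to library depth (RPM), so no value has a replicate error, and intervals below cover counting error only. The RPM steps placed the pooled depth at 280714967 IP and 364905848 input reads for m1A, 118320068 and 241116540 for m5C, and 263344365 and 259416505 for m7G. For ac4C the depth was 17135274 IP and 333220800 input reads. The Psi list came from 10921552 tags, of which 2218798 were left after filtering. Below, a gene's RPM ratio, lower bound or Psi fold is that of 1 peak, the one with the highest authors' value. Coordinates are those of hg38, as the authors listed them, and the log2 enrichment or fold of a peak is the authors' own value, used only to rank peaks within its list; it is not the log2 of the RPM ratio, which was below 1 for 33.0% of m1A, 49.7% of m5C and 27.7% of m7G peaks.

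m1A peaks were listed in 8262 protein-coding genes, with the strongest enrichment in TNKS1BP1, the antisense RNA STXBP5-AS1, CADM4, DDAH1 and FOXP4. The TNKS1BP1 peak on chromosome 11 (57299692 to 57299891) held 563 IP reads and 0 input reads, at least 244-fold higher in the IP against a floor of 3 pooled input counts. STXBP5-AS1 had 1273 IP and 0 input reads, at least 552-fold higher. CADM4, a cell adhesion gene on chromosome 19 (43622368 to 43622567), had 629 IP and 12 input reads, an RPM ratio of 68.1 (95% exact counting interval 38.7 to 133). PKD1, the polycystin gene, was at least 419-fold higher, and FOXP4 at least 256-fold higher. Other genes among the 10 highest included POLR2E, ARHGAP39 and TRIM65. Among genes for handling m1A, 9 of 13 carried an m1A peak, including TRMT6 and TRMT10C, which take part in tRNA methylation, the demethylase genes ALKBH3 and FTO, and YTHDF1, YTHDF2 and YTHDF3. Their RPM ratios ran from 0.749 (0.709 to 0.790) for RRP8 to 53.7 (45.7 to 63.4) for ALKBH7. The highest summed IP signal was that of NCL, the nucleolin gene, at 15098 RPM against 16937 in the input. RRBP1 had 10941 against 2628 RPM, MYH9 9393 against 828 RPM and APOE 5304 against 625 RPM. Of the 29708 peaks, 18008 had a higher RPM in the IP than in the input, 8399 had a lower one and 3301 did not differ, by an exact binomial test on the recovered pooled reads with Benjamini-Hochberg adjustment. That test compares these pooled libraries, not conditions, and the authors' log2 enrichment was above 0 for every listed peak.

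m5C peaks were listed in 7881 protein-coding genes, and MALAT1, a nuclear long non-coding RNA, had the highest summed IP signal. Over 6 peaks it reached 58322 RPM in the IP and 7025 RPM in the input. TALAM1, annotated antisense to it, was listed at 57142 against 6646 RPM, and whether these reads came from 1 strand or both is uncertain. HSP90AA1, a heat shock chaperone gene, followed with 17715 against 4905 RPM, then EIF5B with 11429 against 1453 RPM and NOP58 with 8655 against 382 RPM. By enrichment, PRR7 ranked highest, with 244 IP and 0 input reads on chromosome 5 (177445995 to 177446094), at least 166-fold higher. TTC17 had 2323 IP and 19 input reads, an RPM ratio of 249 (159 to 415). The peaks of IQCK and GPRC5B lie on opposite strands at nearly the same place on chromosome 16 (19857636 to 19857810 for IQCK), so their assignment is uncertain. TARS1, LTBP1 and BTNL8 were also among the 10 highest. Among genes for handling m5C, 10 of 15 carried an m5C peak, including the methyltransferase genes NSUN2, NSUN3, NSUN4, NSUN5 and NOP2 and the dioxygenase genes TET1, TET2 and TET3. At each gene's peak of highest enrichment, IP signal did not always exceed input signal, with RPM ratios of 20.5 (13.4 to 32.6) for TET2, 3.37 (3.10 to 3.66) for NSUN4 and 0.388 (0.240 to 0.604) for NSUN2. In recovered reads scaled to depth, 9274 of 21827 peaks were higher in the IP, 9287 were lower and 3266 did not differ by the exact binomial test.

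m7G peaks were listed in 7197 protein-coding genes, led by TARS1, a threonyl-tRNA synthetase gene, and USP7, a deubiquitinase gene. The TARS1 peak on chromosome 5 (33440771 to 33440795) held 130 IP and 0 input reads, at least 42.7-fold higher, and was listed at the same coordinates for m5C. USP7 was at least 18.4-fold higher. PANK2, a pantothenate kinase gene, had 239 IP and 6 input reads, an RPM ratio of 39.2 (17.8 to 108). SRGAP2C, one of several near-identical copies of SRGAP2, had a ratio of 28.5 (17.8 to 48.4) and is uncertain for that reason. PASK and PPP1R7 peaks overlap on opposite strands of chromosome 2 and are uncertain as well. SLC30A6, MSL3 and CARD8 completed the named protein-coding genes of the 10 highest. All 10 genes of the m7G list carried an m7G peak, and all 10 carried an m1A and an m5C peak as well. Among them were METTL1 and WDR4, the tRNA m7G methyltransferase complex, BUD23 and TRMT112, and RNMT and RAMAC of the cap methyltransferase. EIF4E, the cap-binding translation factor, was another, with an RPM ratio of 8.22 (7.81 to 8.64). NCL at 9647 against 8285 RPM, HSP90AB1 at 6826 against 6376 RPM and RPL23A at 6560 against 2946 RPM had the highest summed signal. In recovered reads scaled to depth, 11213 of 16942 peaks were higher in the IP, 3640 were lower and 2089 did not differ.

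ac4C peaks were listed in 4432 protein-coding genes, and the strongest had almost no input reads. ZFHX4, a homeobox gene on chromosome 8 (76842691 to 76849088), had 334 IP and 2 input reads, an RPM ratio of 3248 (892 to 26927). CCDC80 had 286 IP and 1 input reads, a ratio of 5562 (990 to 220434). GUCY1A1, a guanylate cyclase subunit gene, was at least 1815-fold higher, LAMA2, a laminin gene, at least 1608-fold higher, DAG1 at least 1452-fold higher and the long non-coding RNA HOTTIP at least 1245-fold higher. ZNF462 and RNF32 were among the 10 highest too, as were C8orf88 and NECAB1, whose peaks coincide on opposite strands. Of the 3 genes in the ac4C list of enzymes and partners, NAT10, the acetyltransferase, had an RPM ratio of 23.9 (10.8 to 54.1) from 16 IP and 13 input reads, and SIRT7, a sirtuin deacetylase gene, had one of 21.4 (17.7 to 25.8), whereas THUMPD1 had no listed peak. HSP90AA1 at 8603 against 3139 RPM, PTMA at 6148 against 2479 RPM and NPM1 at 5413 against 2662 RPM had the highest summed signal. Of 27 genes known as markers of fibroblasts and other mesenchymal cells, 13 had an ac4C peak with 3 or fewer input reads. That marker list was not fixed beforehand but written after 3 collagen genes had been seen among these peaks. VIM, the most abundant of these markers in the ac4C IP, had 612 RPM there against 2.34 in the input, from 779 input reads over 2 peaks. All 8463 peaks were higher in the IP by the exact binomial test. Each had been listed with an authors' log2 enrichment of at least 0.105 in these same libraries, so this is no independent support for enrichment. Summed over listed peaks, IP values came to 18.7% of the IP depth for ac4C, 82.2% for m1A, 88.4% for m5C and 74.0% for m7G. Reads under peaks that coincide on opposite strands may enter these sums more than once.

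Psi peaks were listed in 6094 protein-coding genes, and the strongest lay in small nucleolar RNA genes. SNORD3B-1 on chromosome 17 (19062079 to 19062126) had the highest fold over local background, 18.6, and SNORD3A had 17.7; both are near-identical copies of U3, so reads could not be assigned to 1 of them with certainty. RYR2 at 16.6, SLCO5A1 at 16.4, SORCS2 at 15.7 and PHF24 at 15.7 were the highest protein-coding genes apart from RPL10 at 16, which shares sequence with its pseudogene RPL10P6 at 15.5. ALB, the albumin gene, reached 14.8 and ITIH2 14.3. Of 16672 peaks, 11854 lay in protein-coding genes, 1499 in pseudogenes, 1098 in long non-coding RNA genes and 74 in tRNA genes. Among 16 pseudouridine synthase genes and partners, 6 carried a Psi peak: DKC1, the dyskerin gene, its partners NOP10 and GAR1, and PUS1, PUS7L and TRUB1. These peaks were called without a control library and without strand, and no test of IP against input was possible. The pileup of Psi peaks was low, with a median of 4 and a maximum of 31 over the list. A peak was given to a gene by the gene's whole span, introns included, so a fold does not place it in the mature RNA.

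Many genes carried listed peaks of several modifications. Of 11557 protein-coding genes with any peak, 1692 were in all 5 lists and 2653 in 1 list alone. These counts keep every listed peak. By the exact binomial test, 28.3% of m1A, 42.5% of m5C and 21.5% of m7G peaks had a lower RPM in the IP than in the input. Psi peaks were called without a control. Genes of all 5 lists with the smallest rank sums included PSMD11, LPP, VKORC1L1, TAB2, COPA, ANKRD28, IGF2BP3, ASH1L and PGAP2. PSMD11 encodes a proteasome subunit and COPA a coat protein of vesicles. The m5C peaks had RPM ratios of 53.0 (44.2 to 63.9) for IGF2BP3 and 23.3 (20.7 to 26.2) for LPP. m1A and m7G had the highest odds ratio of the 10 pairs, 22.1 (95% CI 19.8 to 24.7), with 6497 genes in both. m1A and m5C shared 6648 genes (odds ratio 15, 13.5 to 16.7), and m5C and m7G shared 5792 (7.04, 6.43 to 7.70). ac4C and Psi shared 2346 genes, with the lowest odds ratio, 1.74 (1.60 to 1.88). All 10 pairs were above 1 by Fisher's exact test, two-sided, with a background of protein-coding genes listed for a modification outside the pair, and the largest adjusted p was 2.1e-40. Within 5 strata of input reads per base the odds ratios were smaller, 5.92 for m1A and m7G, 4.60 for m1A and m5C, 1.90 for m5C and m7G and 1.47 for ac4C and Psi, and all 10 pairs still passed. For pairs without Psi the strata also left out genes listed for Psi alone, and that change of background by itself gave 16.3 for m1A and m7G, 9.88 for m1A and m5C and 4.34 for m5C and m7G.

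**Figure D1:**
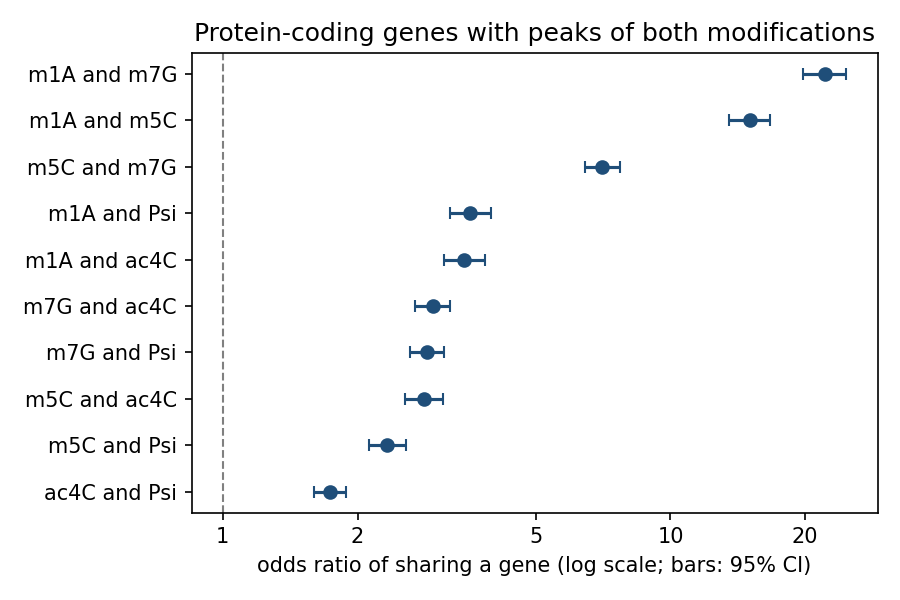
Odds ratio (log axis) of a protein-coding gene having peaks of both modifications, for each of the 10 pairs, with bars for the 95% CI and a dashed line at 1. m1A and m7G lie highest at 22.1 and ac4C and Psi lowest at 1.74.

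Peaks of m7G, ac4C and Psi lay near the annotated 5' ends of genes more often than the same peaks placed at random in stretches that the other lists mark as transcribed. For m7G, 19.6% of midpoints were within 500 bases of the 5' end against 11% placed (SD 0.242), and 3.22% were near the 3' end against 5.86%. ac4C had 21.4% against 13.1% at the 5' end and 3.87% against 6.06% at the 3' end. Psi had 22.1% against 12.9% at the 5' end. m5C peaks were more frequent near 3' ends, 6.34% against 4.90%, and m1A peaks slightly less frequent there, 6.72% against 7.45%. In each of these 7 cases the permutation p was 0.001, the smallest that 1000 placements can give (two-sided, adjusted p = 0.00143 over 10 tests). The 5' shares of m1A (adjusted p = 0.14) and m5C (adjusted p = 0.198) and the 3' share of Psi (adjusted p = 0.305) did not pass the permutation test. The 5' shares of m1A and m5C passed in opposite directions under other settings, with ratios of 1.10 and 1.2 by most of a peak's bases and of 0.769 and 0.888 with the stretches of all 4 lists, and the 3' share of Psi passed with a window of 1000 bases (ratio 0.895, adjusted p = 0.00375 by permutation). Only 39.6% (ac4C) to 65.7% (m7G) of the peaks of coding genes lay in stretches where they could be placed. Both ac4C calls ended when the stretches of all 4 lists were used (ratio 1.03, adjusted p = 0.339, and ratio 0.981, adjusted p = 0.644, by permutation), and the m1A call ended with a window of 200 bases (ratio 0.989, adjusted p = 0.832 by permutation) and when the end was given by most of a peak's bases (ratio 0.998, adjusted p = 0.957 by permutation).

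**Figure D2:**
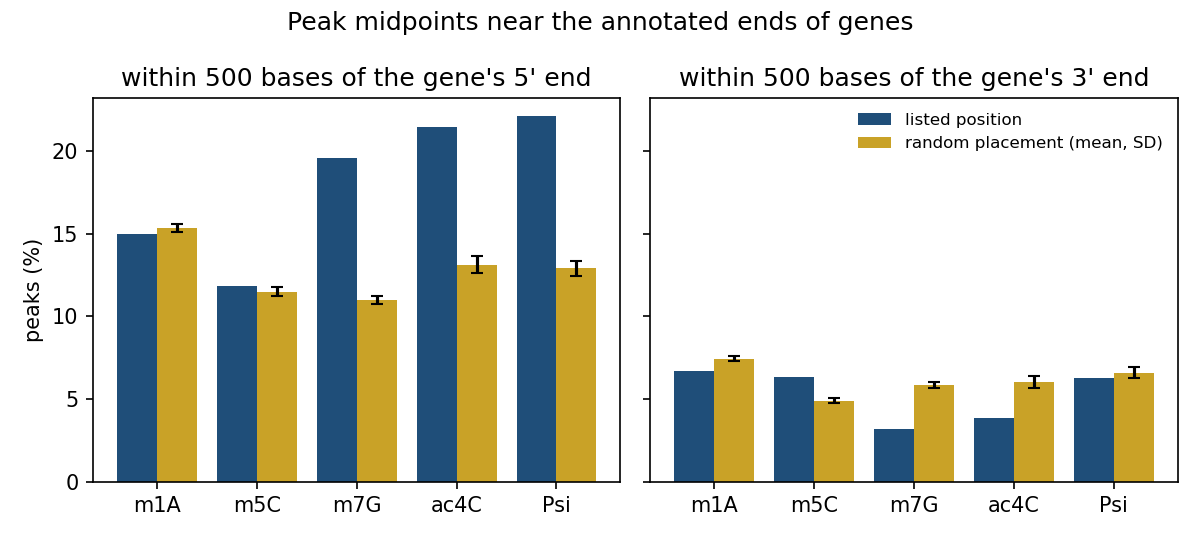
Percent of peak midpoints within 500 bases of the annotated 5' end (left) or 3' end (right) of the gene, for each modification, as listed (blue) and as the mean of 1000 random placements (yellow, bars SD). m7G, ac4C and Psi stand above their placements at the 5' end, 19.6% against 11% for m7G.

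Peak overlap was examined within genes that carried listed peaks of both modifications, among peaks in stretches listed outside the pair. Psi and m7G peaks had the highest ratio of overlap to placement. In 2001 genes, 62.9% of Psi peaks overlapped an m7G peak by 1 base or more, against 43.8% placed at random (SD 0.703), a ratio of 1.44. ac4C peaks overlapped Psi peaks in 21.4% of cases against 16.4% (ratio 1.30). Psi with m5C (1.17), ac4C with m7G (1.11) and Psi with m1A (1.06) were also above placement. m5C with m1A (73.8% against 81.0%, ratio 0.911) and m7G with m1A (77.7% against 80.6%, ratio 0.964) were below it. All these shares cover only peaks that could be placed, 4915 in 2819 genes for m5C with m1A. Each of these 7 pairs had the smallest permutation p (adjusted p = 0.00143 over 10 tests). Peaks of m7G, ac4C and Psi also lay near 5' ends above placement, and a shift along the gene does not keep that position. Overlap above placement between these lists can therefore arise from a shared lean to 5' ends, which was not tested. ac4C with m1A (adjusted p = 0.0674), m7G with m5C (adjusted p = 0.332) and ac4C with m5C (adjusted p = 0.655) did not pass the permutation test, but all 3 passed below placement with stretches of all 4 lists (0.586, 0.755 and 0.507), as did m7G with m5C among peaks above median significance (0.910, adjusted p = 0.00143 by permutation). These directions depended on the definition: when the overlap had to cover 50% of the shorter peak, all 10 pairs were above placement, m5C with m1A at 1.06 and m7G with m1A at 1.12. With stretches of all 4 lists, which hold more peaks, ac4C with m7G fell below placement, at 0.612 (32.2% of 5766 peaks against 52.5%), and ac4C with Psi (0.941, adjusted p = 0.157 by permutation) and Psi with m1A (adjusted p = 0.6 by permutation) no longer passed.

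With the full lists, genes of translation and splicing carried listed peaks more often than other transcribed genes. Within strata of input level, 1 of these 10 calls held with a finite odds ratio, and calls that gave none were not judged. Genes for plasma proteins almost never carried an ac4C peak. Of 48 genes for plasma proteins that hepatocytes secrete, 38 had an m1A peak, 37 an m7G peak, 32 an m5C peak and 31 a Psi peak, but 3 an ac4C peak: C5, HP and A1BG. ALB had 4 m1A, 3 m5C, 4 m7G and 9 Psi peaks and 0 ac4C peaks, and APOA1 and TF had 0 ac4C peaks as well. Among background genes, 7.14% of plasma protein genes had an ac4C peak against 35.8% of all (odds ratio 0.137, 95% CI 0.0424 to 0.444, adjusted p = 0.000316 by Fisher's exact test). The same ac4C list held 13 of 27 fibroblast and mesenchymal marker genes in peaks with 3 or fewer input reads. Those markers were listed after some of them had been seen there. Translation factor genes passed for all 5 modifications, with odds ratios of 4.86 for m1A, 3.33 for m5C, 5.32 for m7G, 4.42 for ac4C and 2.39 for Psi. Examples were PABPC1, a poly(A)-binding protein gene (m1A RPM ratio 15.2, 14.7 to 15.8), EIF4G1 (m7G ratio 12.5, 11.2 to 13.9) and EIF5 (ac4C ratio 22.3, 18.3 to 27.1). Spliceosome and SR protein genes also passed for all 5, with odds ratios of 6.67 for m1A and 5.93 for Psi. Their examples included HNRNPU (m5C ratio 6.57, 4.36 to 10.2), SRSF7 (m5C ratio 16.7, 9.90 to 30.1) and HNRNPM with a Psi fold of 11. Within 5 strata of input reads per base, translation factor genes passed for ac4C (odds ratio 3.47). The odds ratios of 1.47 for m5C, 2.52 for m7G and 1.09 for Psi did not pass. Spliceosome genes passed there for none of the modifications with an odds ratio, at 1.11 for m5C, 2.29 for ac4C and 2.62 for Psi. For m1A, neither list gave an odds ratio within strata, nor did spliceosome genes for m7G. No gene of the list in those strata lacked a peak, so the odds ratio had no finite value. Whether these calls held was therefore not judged. HBV host factor genes passed for all 5 with the full lists, with 32, 33, 31, 22 and 24 of 40 genes carrying m1A, m5C, m7G, ac4C and Psi peaks. None of these 5 calls held when only peaks above each list's median significance were kept (adjusted p from 0.0525 for ac4C to 0.498 for m5C by the exact test) or within 5 strata of input reads per base. Among them were HNF4A, a hepatocyte transcription factor gene (at least 17.8-fold higher for m1A, Psi fold 11), RXRA (m1A ratio 3.99, 3.31 to 4.83) and APOBEC3B (m7G ratio 5.95, 4.96 to 7.19).

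Cytosolic ribosomal protein genes passed for m1A (71 of 79), m5C (67 of 79) and m7G (71 of 79, odds ratio 7.33), not for ac4C (adjusted p = 0.179 by Fisher's exact test) or Psi (adjusted p = 0.0817 by the exact test). None of the 3 calls held within 5 strata of input reads per base, where the direction turned for m1A (odds ratio 0.624) and m5C (0.836) and m7G stood at 1.37. RPL38 (m5C ratio 32.8, 20.1 to 57.2) and RPS19 (m7G ratio 9.26, 8.75 to 9.80) were examples. Genes for oxidative phosphorylation passed for m1A (53 of 62) and m7G (53 of 62), with CYC1, a respiratory chain gene, at an m1A ratio of 145 (61.7 to 448) and ATP5MC2 at an m7G ratio of 12.8 (11.6 to 14.2), and within strata neither call held, at 0.794 for m1A and 2.61 for m7G. Cell cycle genes passed for m1A, m7G and ac4C. MKI67, a proliferation marker (m1A ratio 26.5, 15.2 to 50.4), TTK (m7G ratio 8.67, 7.27 to 10.4) and FOXM1 (ac4C ratio 33.7, 20.3 to 56.8) were among them. Plasma protein genes passed for m1A, m7G and Psi, hepatic lipid and sterol genes for m7G and Psi, and heat shock and unfolded protein genes for m7G and Psi. ACLY, a lipid synthesis gene, had a Psi fold of 12.2. The m6A genes passed for m1A, m5C and m7G, with 16 of 16 carrying an m1A peak, including IGF2BP1 (m5C ratio 65.4, 51.7 to 84.1). The m7G genes and the pseudouridine synthase genes passed for m7G. Replication-dependent histone genes were lower for m1A (1 of 55, H4C3, odds ratio 0.0376, 0.00486 to 0.292). They also passed as lower for ac4C (1 of 55, H1-5, which lay outside the background). There the odds ratio was 0.0778 with a CI of 0.00459 to 1.32, which includes 1 (adjusted p = 0.0298 by Fisher's exact test). Only 12 and 11 histone genes were in the m1A and ac4C backgrounds. Odds ratios for m5C (0.287), m7G (0.831) and Psi (0.242) were below 1 as well but did not pass. Glycolysis genes, innate RNA sensing genes, m1A genes, m5C genes, ac4C enzyme genes and genes of other liver cell types passed for no modification. The background leaves out genes found in the tested list alone, so the ac4C tests held 7 of the 10 glycolysis genes with an ac4C peak, without LDHB, PFKM and PFKP, and 1 of the 4 genes of other liver cell types, without COL1A1, COL1A2 and COL3A1.

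Over all 95 tests (Fisher's exact test, two-sided), 35 were higher and 3 lower than background at an adjusted p under 0.05; adjusted over the list alone, 35 were higher and 3 lower. The calls that differed were pseudouridine synthase genes for m7G, which did not pass over the list alone (adjusted p = 0.0684 by the exact test), and ribosomal protein genes for Psi, which did (adjusted p = 0.043 by the exact test). By modification, higher and lower counts were 8 and 1 for m1A, 5 and 0 for m5C, 12 and 0 for m7G, 4 and 2 for ac4C, and 6 and 0 for Psi, and differences between modifications in these calls were not tested, apart from plasma protein genes. Within 5 strata of input reads per base, 2 of the higher calls passed with an odds ratio, translation factors and cell cycle genes for ac4C (3.47 and 3.99). Calls in which no list gene of the strata lacked a peak gave no odds ratio and were not judged. Some calls ended there with odds ratios that were large, 18.9 for lipid and sterol genes in m7G (3.59 without strata), 4.64 and 2.97 for cell cycle genes in m7G and m1A and 3.86 for HBV host factor genes in m5C. Plasma protein genes for ac4C (0.103) and histone genes for m1A (0.115) stayed lower, and cell cycle genes for m5C were lower there (0.250). With peaks above median significance alone, calls were also lost for oxidative phosphorylation, m6A and cell cycle genes in m1A, for lipid, pseudouridine synthase and m6A genes in m7G and for histone genes in ac4C.

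**Figure D3:**
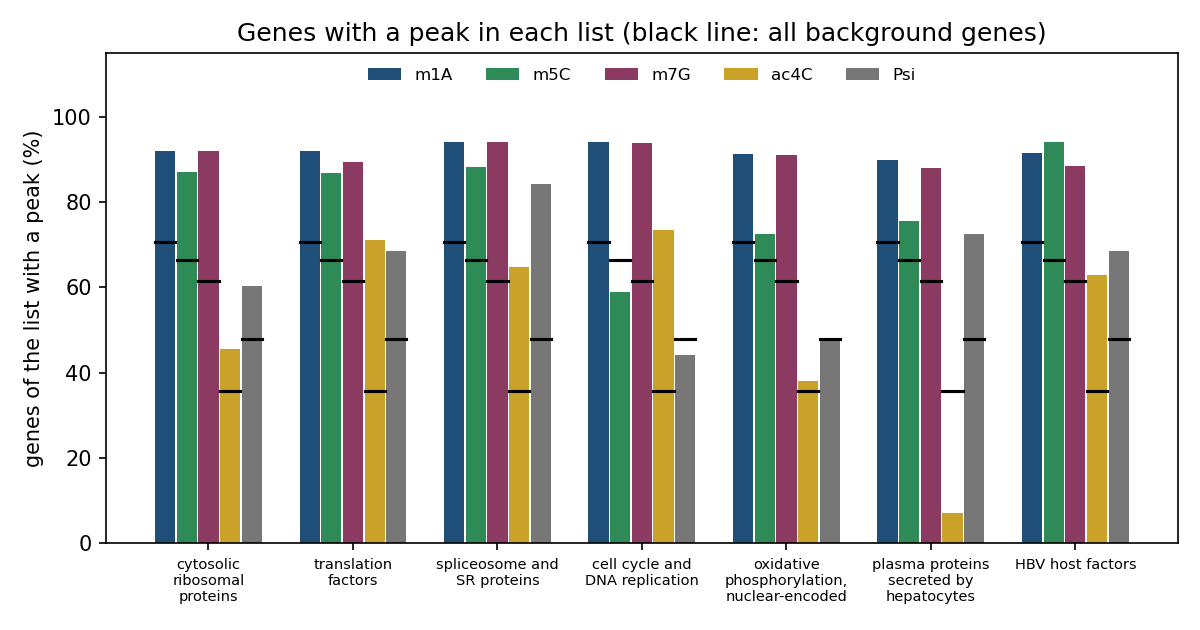
Percent of background genes in each of 7 fixed gene lists with a peak of each modification (bars), with the percent among all background genes as black lines. For plasma proteins, 7.14% carried an ac4C peak against 35.8% of all background genes.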

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

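All tests of differences between lists in this part were chosen after the values were seen, as was the test of cell type lists. The tests of IP reads per peak and of the same genes in other lists were set before their results were seen.

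Genes for plasma proteins differed from other protein-coding genes in how ac4C compared with each other list. Among genes found in 1 of 2 lists, Fisher's exact test (two-sided, adjusted over 4 comparisons) set plasma protein genes against the rest, so that list length does not decide it. Between ac4C and m1A, 1 plasma protein gene was only in ac4C and 36 only in m1A, against 966 and 4761 other genes (odds ratio 0.137, 95% CI 0.0187 to 0.9997, adjusted p = 0.0146 by the exact test). For m5C the counts were 1 and 30, against 1154 and 4574 (adjusted p = 0.0146 by the exact test). For m7G they were 0 and 34, against 1291 and 4022 (adjusted p = 0.000296 by the exact test), and for Psi 1 and 29, against 2085 and 3719 (adjusted p = 0.000237 by the exact test).

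Peaks with 3 or fewer pooled input reads were far more frequent in the ac4C list, 651 of 8463, than in the m1A list (106 of 29708, odds ratio 23.3, 95% CI 18.9 to 28.6), the m5C list (247 of 21827, odds ratio 7.28, 6.27 to 8.45) and the m7G list (4 of 16942, odds ratio 353, 132 to 943), by Fisher's exact test. Counting noise was argued against, since 99.1% of the 651 peaks held more than 10 IP reads (median 64, range 10 to 638); the list holds no ac4C peak with under 10, but of Poisson counts of 10 or more at the rate of 3 input reads, 1.40% would exceed 10. A candidate explanation is RNA from fibroblast-like or other mesenchymal cells in the ac4C IP: 13 of 27 marker genes were among the 404 protein-coding genes of these peaks (odds ratio 46.6, 95% CI 21.8 to 99.9, adjusted p = 5.77e-15 by Fisher's exact test over 5 lists), against 0 of 18 neuronal, 0 of 16 blood, 0 of 12 endothelial and 0 of 12 squamous genes. That marker list was written after COL1A1, COL1A2 and COL3A1 had been seen there; without these 3 genes, 10 of 24 were there (odds ratio 35.9), and of the 27, 18 had any ac4C peak, 8 had an m1A, m5C or m7G peak, 5 were in the fixed list of other liver cell types and 0 in another marker list. The neuronal, blood, endothelial and squamous lists were short, with upper 95% CI limits of their odds ratios from 21.8 to 32.9. Finding 0 of their genes therefore does not exclude odds ratios well above 1. The most abundant mesenchymal markers, summed over peaks of any input level, were VIM at 612 RPM in the IP against 2.34 in the input (779 reads), COL5A2 at 202 against 1.87, POSTN at 182 against 0.669 and COL3A1 at 167 against 0.585. Whether the cells themselves express these genes and the ac4C input lacked them stays open, as 29.0% of the 404 genes, and 17.6% of the 245 with no other ac4C peak, had an m1A, m5C or m7G peak, against 90.9% of the 4187 genes with an ac4C peak of more than 3 input reads, and no biological explanation was tested.

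The Psi list held 21 peaks on the mitochondrial genome, outside the comparisons: 6 in ND5, 4 in CYTB, 3 each in ND1 and ND2, 2 in ND6, 1 each in ATP6 and RNR2, and 1 outside genes. A contig with ribosomal DNA held 24 Psi peaks, 19 m5C peaks, 11 m7G peaks, 2 m1A peaks and 0 ac4C peaks. The Psi list held 24 more, 48 in all, on a second such contig, where each antibody list held 0. These signals lie outside the genes the comparisons use. No control library was analysed for the Psi peaks, whereas each antibody peak has a pooled input value.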

How the results depend on the processing

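Chosen after the data were seen were the tests within strata, the binomial test, gene assignment by span, peaks of several genes, backgrounds without Psi, the tests without parts of the ac4C data, the windows of 200 and 1000 bases and the stretches of all 4 lists. Where no reason is given, the cause was not tested. No paired analysis was possible because each list holds 1 pooled value per peak. For the same reason leaving out replicates, a replicate block, another count model and a filter on low counts were not run; strata of exonic length, placement within the same transcript feature and base composition were not run for want of an exon table and genome.

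All 10 gene-sharing odds ratios stayed above 1 and passed in all 7 alternatives. For pairs with Psi, the alternative without Psi in the backgrounds is the main test again and could not change. Keeping peaks above each list's median significance left 14854 m1A, 10913 m5C, 8471 m7G, 4231 ac4C and 8336 Psi peaks by construction, and 2738 ac4C and 3689 Psi genes. With all protein-coding genes as background, 58 gene list tests were higher and 6 lower; without the ac4C list, where fewer tests were run, 23 and 1. Within 5 strata of input reads per base 2 were higher, 26 of the 38 calls no longer passed and 5 gave no odds ratio. In those 5 no list gene of the strata lacked a peak, so they were not judged. Another 3 turned direction, ribosomal protein genes for m1A (0.624) and m5C (0.836) and oxidative phosphorylation genes for m1A (0.794), none of them passing. The cause was not tested.

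Peak overlap depended on the setting. With 50% of the shorter peak required, 10 pairs were higher and 0 lower, and m5C with m1A (1.06) and m7G with m1A (1.12) turned direction; the cause was not tested. With stretches of all 4 lists, 2 pairs were higher and 6 lower, and ac4C with m7G (0.612) and ac4C with Psi (0.941) turned direction; over more peaks (5766 in place of 2549, and 2711 in place of 1550) the observed overlap was lower (32.2% and 14.5%) and the placed overlap nearly as before (52.5% and 15.4%); the cause was not tested. At gene ends no call turned direction. Of other single results, 109 kept their call and 13 lost it under settings chosen before the data were examined, 238 and 50 under those chosen later. Some of the kept calls could not change, such as the 5' share of Psi, whose main placement already used the stretches of all 4 lists. The binomial test left 18008 m1A, 9274 m5C and 11213 m7G peaks with a higher RPM in the IP, and all ac4C peaks. The cause was not tested. Among the antibody lists the ac4C IP was the shallowest, with 17135274 reads, and Psi peaks rested on 2218798 tags.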

Other observations

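In this part the tests of a single scaling factor, of base composition and of strand were chosen after the result was seen; that of input reads was set before.

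The glycolysis genes LDHB, PFKP, PFKM and HK1 had ac4C peaks but 0 m1A, 0 m5C and 0 m7G peaks. The first 3 had 0 Psi peaks too, so the background of the list's ac4C test, which used 19 of 25 genes, left them out; against all protein-coding genes the list did not pass (odds ratio 2.35, 95% CI 1.06 to 5.24, adjusted p = 0.0668 by Fisher's exact test). The collagen genes COL1A1, COL1A2 and COL3A1, markers of mesenchymal cells, had 7, 3 and 10 ac4C peaks and 0 in those 3 lists as well. Of 27 such markers, listed after these collagen genes had been seen, 13 had an ac4C peak with 3 or fewer input reads. LDHB, a lactate dehydrogenase gene, had 415 RPM in the IP against 2.44 in the input at its strongest peak (ratio 170, exact counting interval 158 to 183), an input above the list's median of 0.315 RPM per peak. PFKP, a phosphofructokinase gene, had a ratio of 419 (276 to 666) and PFKM one of 203 (112 to 403), and HK1, a hexokinase gene, was at least 233-fold higher. Other genes whose strongest ac4C peak lay below that median input were SEL1L, of protein quality control at the endoplasmic reticulum (ratio 413, 213 to 916), TET2 (ratio 350, 165 to 888) and POLK (ratio 136, 87.6 to 221).

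Psi peaks lay in families of near-identical non-coding genes, named here after their values were seen. The 7SL family of the signal recognition particle had 22 peaks in 20 genes and copies, with a highest fold of 14.7. There were 10 peaks in 10 tRNA-Asp genes (highest fold 14.9), 18 in 18 SNAR genes (highest fold 12.1) and 5 in 4 U3 genes. Reads of such copies cannot be assigned with certainty.

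The authors' log2 enrichment and the log2 of the RPM ratio differed by a median of 1.54 for m1A, 2.91 for m5C, 0.76 for m7G and -0.54 for ac4C, and the RPM ratio was below 1 for 33.0% of m1A, 49.7% of m5C and 27.7% of m7G peaks. A single scaling factor per list was argued against, since the SD of the difference over peaks was at least 0.336 in each list. Spearman rho of the difference with input reads was 0.296 for m1A, 0.0134 for m5C, 0.186 for m7G and 0.0642 for ac4C. These values were below the size set beforehand for shrinkage of peaks with few input reads. They cannot decide on it, since peaks without input reads were left out and shrinkage can move a ratio either way. Over 22 autosomes the median difference followed gene density, with Spearman rho -0.848 for m1A, 0.837 for m5C, -0.842 for m7G and -0.875 for ac4C (permutation p = 1e-05, the smallest 100000 permutations can give, adjusted p = 1e-05 over 4 relations), Pearson r of -0.880, 0.774, -0.805 and -0.880 (permutation p of 1e-05 to 3e-05), and r of -0.836, 0.848, -0.872 and -0.778 without the 2 chromosomes farthest in density. A correction for base composition may therefore be part of the authors' values; gene density only stands in for base composition, and no biological explanation was tested.

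Peaks on opposite strands with both ends within 30 bases of each other had nearly equal IP reads. Within 0.2 on the log2 scale were 73.1% of 130 couples for m1A, 82.0% of 167 for m5C, 68.9% of 103 for m7G and 45 of 60 for ac4C, against 3.82% to 6.86% of random couples. Reads may have been counted without regard to strand, which would leave MALAT1 and TALAM1, IQCK and GPRC5B, PASK and PPP1R7, and NECAB1 and C8orf88 unresolved. No biological explanation was tested.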
